A study of Homo sapiens with 9 samples.

How the data were processed

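Gene expression was measured by RNA sequencing in TC32, an established Ewing sarcoma cell line. There were 9 libraries in 3 groups of 3. Vehicle cells received neither the ligand nor the inhibitor. Wnt3a cells were exposed to Wnt3a for 28 h. The cells called inhibitor cells below received Wnt3a for the same 28 h, with SB-505124, which blocks the kinases of the TGF-β and activin type I receptors, present for the last 24 h. Libraries of polyadenylated RNA were made with a stranded kit, per the labels' protocols. Groups and replicate numbers were taken from the labels, and all 9 libraries were mapped to a group. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No group received the inhibitor without Wnt3a.

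Read processing was done by the authors. Per the submitters' processing notes, it used CASAVA 1.8.2, Trimmomatic 0.36, STAR 2.5.2a, RSEM 1.2.31 and the genome build hg38. The annotation release, the strand setting of the counting and any filter on genes are not given in the sources used here. Per the file headers, each library has a gene table with the expected count per gene, which RSEM estimates by sharing out reads that fit several genes or transcripts. Per the file headers, the same tables hold TPM and FPKM made by the authors, and a length and an effective length per gene. TPM entered 1 alternative test, FPKM was not used, and effective length entered 1 alternative and a separate test described at the end. Each table had 58278 rows. After the 45 second rows for pseudoautosomal genes were added to their partners there were 58233 gene IDs, of which 57895 (99.4%) were found in GENCODE release 29, also on hg38, when the version of the ID was ignored and 55067 with the same version. Gene names, gene types and coordinates come from that release. A symbol was shared with another ID by 2156 IDs.

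Expected counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR with the 3 groups, which left 17880. Library sizes were scaled with TMM factors, and 1 model with the 3 groups was fitted to all 9 libraries with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with 6 residual degrees of freedom before moderation. The common biological coefficient of variation was 21.5%. Each comparison was a 2-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested, at an adjusted p threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Values per group are TMM-scaled counts per 1e6 counts of a library (CPM) as mean ± SD of 3 libraries. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with its exact Clopper-Pearson 95% interval. Reads were counted without molecular identifiers, so these floors and intervals cover counting error only.

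Gene lists were tested with camera of limma 3.58.1 on voom values of the same genes, with the preset correlation between genes of 0.01 and adjustment over 35 lists in each comparison. Camera with an estimated correlation and fry were run beside it. The lists covered the pathways of the ligand and of the inhibitor, the extracellular matrix, factors of blood vessel growth, genes reported to respond to the fusion protein of this tumour, proliferation and stress, markers of other cell types, and RNA quality. For each list, members past the edgeR threshold were counted with adjustment over all genes tested and over the list alone. The described lists, 21 besides those for cell types and RNA quality, were chosen from the 35 after their results were seen.

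Genes were named by a rule. It took the 10 largest rises and the 10 largest falls in log2 fold change among genes past the threshold with a mean of at least 1 CPM, a gene symbol that is not a clone name and no overlap between the libraries of the 2 groups, with 5 and 5 for inhibitor against vehicle. It added a fixed panel of 14 genes, of which LEF1 was not among the genes tested, and up to 4 members with the smallest adjusted p of each of 19 of these lists, those in the figure of lists. Only 4 genes fell with Wnt3a, and all are named. Not every gene the rule selects is described. LUM, PDGFRB, THY1 and MT1X, and NKD2 and TCF7 for Wnt3a against vehicle, lie outside the rule and were named after their values were seen. The groups, tests, lists, naming rule and the alternatives not called added below were fixed before the data were examined.

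The alternatives were other size factors (RLE) or library totals alone, other filters on low counts, DESeq2 1.42.0, limma-voom, unrounded expected counts, an offset for effective length, only the 2 groups compared, the replicate number as a block, stricter thresholds, limma-trend on log2(TPM + 1), and leaving out each library in turn. Where a library was left out, the remaining ones carried the estimate of spread. Added after the data were seen were a fit to protein-coding genes only, thinning of every library to the lowest total, a correction of each library for trends with GC content and transcript length, and a fit without vehicle replicate 2 and Wnt3a replicate 2, which deviated from their groups in the same direction.

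The edgeR step was tested on simulated counts for the 17880 genes, with 50 genes changed at each of 4 sizes in each comparison. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery of genes below that was not tested. In Wnt3a against vehicle it called 8, 35, 43 and 48 of the genes changed 1.5, 2, 4 and 8-fold, with 13 false calls among 147. In inhibitor against Wnt3a it called 7, 32, 45 and 49, with 8 false among 141, and in inhibitor against vehicle 7, 32, 44 and 50, with 4 false among 137. Effective lengths were compared with limma on their log2 values over 14085 genes, with the same threshold.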

Results

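The data are gene-level expected counts of polyadenylated RNA from TC32 cells, an Ewing sarcoma line that carries the EWSR1-FLI1 fusion oncogene. The 3 groups of 3 libraries were vehicle, Wnt3a, and Wnt3a with the TGF-β receptor inhibitor SB-505124. Total counts were 34348339, 38637007 and 37577595 in vehicle replicates 1 to 3, 36903919, 40661761 and 42976799 with Wnt3a, and 28844348, 37540072 and 34900919 with the inhibitor. Replicates of a group correlated at 0.969 to 0.986 across genes, and every pair differed by more than sampling noise, with a chi-square per degree of freedom of 7.2 to 64.2. The first principal component, with 56.5% of the variance, parted the 3 inhibitor libraries from the other 6. On the second, with 14.7%, inhibitor replicate 1 lay at -66.9 and inhibitor replicates 2 and 3 at 26.9 and 24.5. The other 6 libraries parted across their groups on it, with vehicle replicates 1 and 3 and Wnt3a replicate 3 at 22.6, 31 and 24.9 and vehicle replicate 2 and Wnt3a replicates 1 and 2 at -8.2, -30.7 and -24.2.

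Several measures of the libraries moved with the inhibitor. Genes with at least 1 count numbered 23196 to 23250 in inhibitor libraries and 25128 to 26802 in the others. The 10 most abundant genes took 7.27% to 7.89% of counts there and 5.75% to 6.57% elsewhere. TMM factors were 0.876 to 0.914 with the inhibitor and 1.02 to 1.10 without it. The share of mitochondrial counts overlapped, at 3.85% to 5.12% with the inhibitor and 4.04% to 4.87% without.

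**Figure D1:**
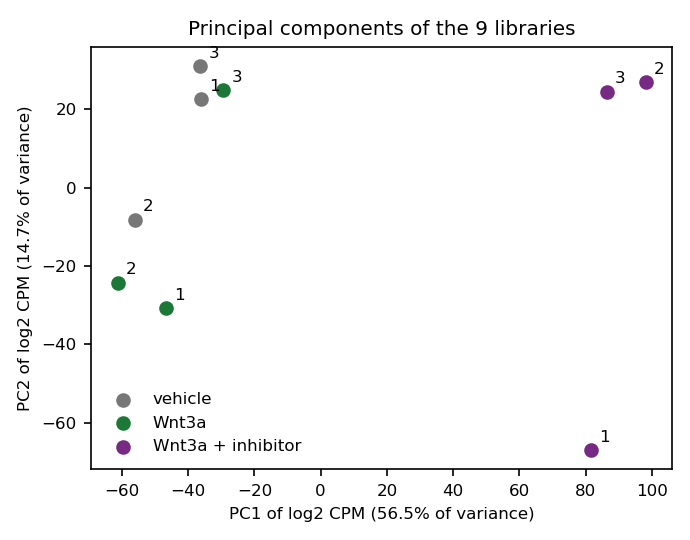
The 9 libraries on the first (horizontal, 56.5% of the variance) and second (vertical, 14.7%) principal components of log2 CPM, coloured by group and numbered by replicate. The inhibitor libraries stand apart on the first component, and inhibitor replicate 1 lies at -66.9 on the second.

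The first comparison, Wnt3a against vehicle, asks what activation of canonical Wnt signalling does in these cells. Several genes that restrain the pathway rose, named singly and not tested as a set. AXIN2, a scaffold of the complex that degrades β-catenin, rose from 3.29 ± 0.326 to 20.1 ± 2.82 CPM (SD, n = 3 per group), a log2 fold change of 2.61 (SE 0.157, edgeR adjusted p = 0.000119). NKD1, which binds Dishevelled and dampens the pathway, rose from 9.33 ± 3.59 to 60.3 ± 17.8 CPM (log2 2.69, SE 0.272, edgeR adjusted p = 0.00299). WIF1, a secreted protein that binds Wnt ligands, rose from 2.05 ± 0.468 to 38.1 ± 7.75 CPM (log2 4.21, SE 0.295, edgeR adjusted p = 0.000308). The zinc finger gene TSHZ1 rose from 5.54 ± 0.130 to 34.3 ± 7.78 CPM (log2 2.63, SE 0.160, edgeR adjusted p = 0.000119). In hg38, AXIN2 (ENSG00000168646.12) spans positions 65528563 to 65561647 of chromosome 17, NKD1 (ENSG00000140807.6) 50548330 to 50649249 of chromosome 16 and WIF1 (ENSG00000156076.9) 65050626 to 65121566 of chromosome 12, and each count sums the transcripts of its gene.

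Of 32 measured Wnt target genes, 6 rose and 0 fell (9 and 1 adjusted over the list alone). They were AXIN2, NKD1, its relative NKD2, the receptor gene FZD7, the transcription factor gene TCF7 and TNFRSF19, a receptor of the tumour necrosis factor family. FZD7 rose from 12.04 ± 1.66 to 27.1 ± 2.88 CPM (log2 1.17, SE 0.140, edgeR adjusted p = 0.00629). TNFRSF19 had 0 counts in vehicle and 87 with Wnt3a, at least 25.9-fold higher (edgeR adjusted p = 0.013). The list passed as higher (camera adjusted p = 8.1e-05), but not with an estimated correlation (camera adjusted p = 0.237). Of 44 ligands, receptors and transducers of the pathway, only WIF1 passed over all genes (3 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0951) except without Wnt3a replicate 1 (camera adjusted p = 0.0225, 0.0225 to 0.312 over the alternatives). FRZB, another secreted Wnt antagonist, had a log2 fold change of 0.47 (edgeR adjusted p = 0.0564) and passed in 6 of 21 alternatives.

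Some matrix genes also rose. COL6A3, a collagen VI chain, rose from 2.18 ± 0.103 to 29.2 ± 12.5 CPM (log2 3.74, SE 0.317, edgeR adjusted p = 0.00115). TGFBI, a secreted adhesion protein named for its induction by TGF-β, rose from 79.1 ± 16.9 to 322 ± 79.8 CPM (log2 2.03, SE 0.198, edgeR adjusted p = 0.00286). MATN3, a matrilin of cartilage matrix, rose from 1.24 ± 0.470 to 15.4 ± 5.66 CPM (log2 3.64, SE 0.376, edgeR adjusted p = 0.00334). COL6A3 (ENSG00000163359.15) lies at 237324003 to 237414375 of chromosome 2 and TGFBI (ENSG00000120708.16) at 136028895 to 136063818 of chromosome 5 in hg38. Of 73 matrix glycoproteins 3 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 9.53e-05, 0.278 with an estimated correlation). Of 30 collagens 1 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.000434, 0.307 with an estimated correlation). COL1A1, a chain of the main fibrillar collagen, had 78.4 ± 33.1 CPM against 27.3 ± 13.3 (log2 1.52, SE 0.375, edgeR adjusted p = 0.189), and COL1A2, its partner chain, a log2 fold change of 1.79 (edgeR adjusted p = 0.148). Neither passed in edgeR, although both did with genes of at least 1 count kept or with DESeq2, and COL1A2 also without Wnt3a replicate 3 (adjusted p over the alternatives as low as 6.82e-06). TNC, the matrix glycoprotein tenascin C, had 1065 ± 280.5 CPM against 565 ± 176 (log2 0.91, SE 0.265, edgeR adjusted p = 0.319), and passed under the same 2 alternatives (adjusted p as low as 0.00131). Of 52 matrix proteases, inhibitors and crosslinkers 0 passed (4 and 0 adjusted over the list alone; camera adjusted p = 0.0737), with TGM2, a crosslinking enzyme, at log2 2.03 (edgeR adjusted p = 0.0794), which passed in 3 of 21 alternatives. That list passed without Wnt3a replicate 2 or 3 (camera adjusted p = 0.0302 and 0.0423, 0.0302 to 0.237 over the alternatives) and as higher with fry (fry adjusted p = 0.0327).

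Among 53 genes commonly induced by TGF-β, TGFBI alone rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.000283, 0.194 with an estimated correlation). The inhibitory SMAD7 had 18.0 ± 0.916 CPM against 13.4 ± 0.821 (edgeR adjusted p = 0.464) and PMEPA1, a feedback gene of the pathway, 48.3 ± 6.66 against 47.2 ± 2.52 (edgeR adjusted p = 0.977). Of 26 ligands, receptors and SMADs of this pathway 2 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00761, 0.278 with an estimated correlation). These were the ligand TGFB2, from 79.2 ± 4.84 to 151 ± 27.7 CPM (edgeR adjusted p = 0.0105), and ITGB8, an integrin subunit that activates latent TGF-β, from 11.5 ± 1.64 to 24.9 ± 1.48 CPM (edgeR adjusted p = 0.0286). The list's call was lost without vehicle replicate 2 or Wnt3a replicate 3 (camera adjusted p = 0.0673 and 0.065, 0.000525 to 0.278 over the alternatives).

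Angiogenesis is named in the title of the series. Of 45 factors that promote blood vessel growth 1 rose and 0 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.223). It was NRP2, a co-receptor for VEGF-C and semaphorins, from 0.662 ± 0.312 to 3.40 ± 0.907 CPM (log2 2.36, edgeR adjusted p = 0.0183). VEGFA, the main endothelial growth factor, had 36.7 ± 6.94 CPM against 33.7 ± 1.49 (log2 0.12, SE 0.158, edgeR adjusted p = 0.928). ANGPTL4, an angiopoietin-like factor, had a log2 fold change of -0.84 (edgeR adjusted p = 0.0535) and passed in 8 of 21 alternatives. Of 25 factors that restrain vessel growth 1 rose and 0 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.0951), namely the matricellular inhibitor THBS1, from 2.42 ± 0.925 to 12.9 ± 1.63 CPM (log2 2.41, edgeR adjusted p = 0.0221). That list passed without Wnt3a replicate 3 (camera adjusted p = 0.0139, 0.0139 to 0.278 over the alternatives).

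Lists of genes reported to respond to EWSR1-FLI1 passed only with camera at the preset correlation. With fry neither passed (fry adjusted p = 0.0953 for the repressed and 0.0939 for the activated list). Of 39 genes reported as repressed by the fusion 2 rose, COL6A3 and THBS1, and 0 fell (11 and 1 adjusted over the list alone; camera adjusted p = 8.1e-05, 0.278 with an estimated correlation). Of 48 reported as activated 0 rose and 1 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.000472, 0.275 with an estimated correlation). This was TRPM4, a sodium-conducting channel, from 78.9 ± 1.8 to 50.6 ± 3.38 CPM (log2 -0.64, SE 0.083, edgeR adjusted p = 0.00964). The fusion targets NR0B1, at 288 ± 50.6 against 387 ± 64.9 CPM (edgeR adjusted p = 0.532), and NKX2-2, at 72.3 ± 14.4 against 99.7 ± 6.57 CPM (edgeR adjusted p = 0.376), did not pass. Of 36 contractile and cytoskeletal genes only the actin-binding CALD1 rose, from 185 ± 6.29 to 315 ± 43.2 CPM (edgeR adjusted p = 0.0288), and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.000117, 0.307 with an estimated correlation). Of 23 YAP target genes only TGFB2 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.000437, 0.18 with an estimated correlation). Among the lists that camera called here, fry called only Wnt targets, TGF-β targets, YAP targets and fibroblast markers (fry adjusted p = 0.0327 for each).

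The lists of this paragraph had no member past the edgeR threshold. Camera gave a lower call for 55 ribosomal protein genes, all below 0 with a median log2 fold change of -0.14 (camera adjusted p = 3.45e-10, 0.307 with an estimated correlation). S phase genes (34; camera adjusted p = 0.0341, 0.732 with an estimated correlation) and interferon-induced genes (32; camera adjusted p = 0.048, 0.619 with an estimated correlation) also had lower calls. The S phase call was lost without vehicle replicate 2 or Wnt3a replicate 2 or 3 (camera adjusted p = 0.146 to 0.28). The interferon call was lost without vehicle replicate 3 or Wnt3a replicate 1 or 2 (camera adjusted p = 0.149 to 0.533), with the highest adjusted p over all alternatives 0.749 and 0.626. The 32 immediate-early genes (camera adjusted p = 0.0814) passed as lower without vehicle replicate 2 or Wnt3a replicate 3, over alternatives that ranged from 5.52e-06 to 0.999. The 40 genes of G2 and mitosis (camera adjusted p = 0.817) passed as lower without Wnt3a replicate 3 (camera adjusted p = 0.0214, up to 0.996 over the alternatives), and their median of 0.03 and mean of 0.01 lay on the other side of 0 from the test. The 23 CDK inhibitors and p53 targets did not pass (camera adjusted p = 0.252). The 34 genes of hypoxia and glycolysis had a lower call (0 and 1 adjusted over the list alone; camera adjusted p = 0.000992, 0.278 with an estimated correlation). The 30 genes of the unfolded protein and amino acid stress response did not pass (camera adjusted p = 0.185), with a median of -0.08 and a mean of 0.003 that differ in sign. They passed as lower without vehicle replicate 2 or Wnt3a replicate 3 (camera adjusted p = 0.012 and 0.00894, 0.00894 to 0.703 over the alternatives).

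Among the remaining large changes, KRT81, a hair keratin whose reads can be shared with near-identical keratins and which is therefore uncertain, had 553 counts with Wnt3a and 1 in vehicle, a ratio of 500 (95% interval 89.4 to 19800; edgeR adjusted p = 0.000391). FOXQ1, a forkhead transcription factor gene, had 135 counts against 2, a ratio of 61 (16.6 to 509; edgeR adjusted p = 0.00286). PARVG, an adaptor of the parvin family, rose from 0.124 ± 0.0648 to 2.80 ± 1.14 CPM (edgeR adjusted p = 0.00931). SYTL2, a synaptotagmin-like vesicle protein, rose from 0.979 ± 0.462 to 7.40 ± 1.57 CPM (edgeR adjusted p = 0.00593). The falls were FOLR2, a folate receptor, from 2.16 ± 0.765 to 0.483 ± 0.164 CPM (log2 -2.16), the dynein gene DNAH11 from 8.83 ± 0.568 to 4.33 ± 0.829 CPM (log2 -1.03), the matrix Gla protein MGP from 429 ± 22.2 to 276 ± 26.1 CPM (log2 -0.64), and TRPM4 (edgeR adjusted p = 0.0428, 0.0428, 0.0487 and 0.00964). The matrix glycoproteins fibronectin, FN1, with log2 0.31 (edgeR adjusted p = 0.786), and SPARC, with log2 0.58 (edgeR adjusted p = 0.667), did not pass.

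Markers of cells that a culture could hold were few among the genes tested. Of 5 endothelial, 5 leukocyte and 6 epithelial markers 0 passed in edgeR in this comparison (camera adjusted p = 0.555, 0.273 and 0.144; 0 and 1 leukocyte markers, 0 of the others, adjusted over the list alone). Of 10 fibroblast markers LUM, a collagen-binding proteoglycan, and COL6A3, which is also in the collagen list, rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.000781, 0.18 with an estimated correlation). PDGFRB and THY1, further members outside the naming rule, were already at 30.9 ± 2.38 and 387 ± 117 CPM in vehicle. The mitochondrial and nuclear RNA lists of RNA quality had 0 members past the threshold (camera adjusted p = 0.832 and 0.817).

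In all, 71 genes rose and 4 fell at an edgeR adjusted p under 0.05, 75 of 17880, with 47 and 2 of them changed at least 2-fold, and 1362 genes had an unadjusted p under 0.05. The count was 26, 48 and 20 without vehicle replicate 1, 2 and 3, 47 and 32 without Wnt3a replicate 1 and 2, 140 without inhibitor replicate 1, which shares the estimate of spread, and 299 with DESeq2. Calls of single genes lost without 1 library were those of FOLR2, ITGB8, CALD1 and MGP without any of the 6 libraries (adjusted p 0.0504 to 0.243). Others were DNAH11 without any but Wnt3a replicate 3 (0.141 to 0.203), and THBS1 without any but vehicle replicate 2 (0.0504 to 0.142). NRP2 was lost without vehicle replicate 2 or 3 or Wnt3a replicate 1 or 3 (0.0515 to 0.129), and TGFB2 without any vehicle replicate (0.0507 to 0.0826). TRPM4 was lost without vehicle replicate 1 or 3 or Wnt3a replicate 1 (0.0507 to 0.0744), TNFRSF19 without vehicle replicate 1 or 3 or Wnt3a replicate 2 (0.0534 to 0.0656) and PARVG without vehicle replicate 3 (0.0759). All are edgeR values, and the highest over all alternatives was 0.429.

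**Figure D2:**
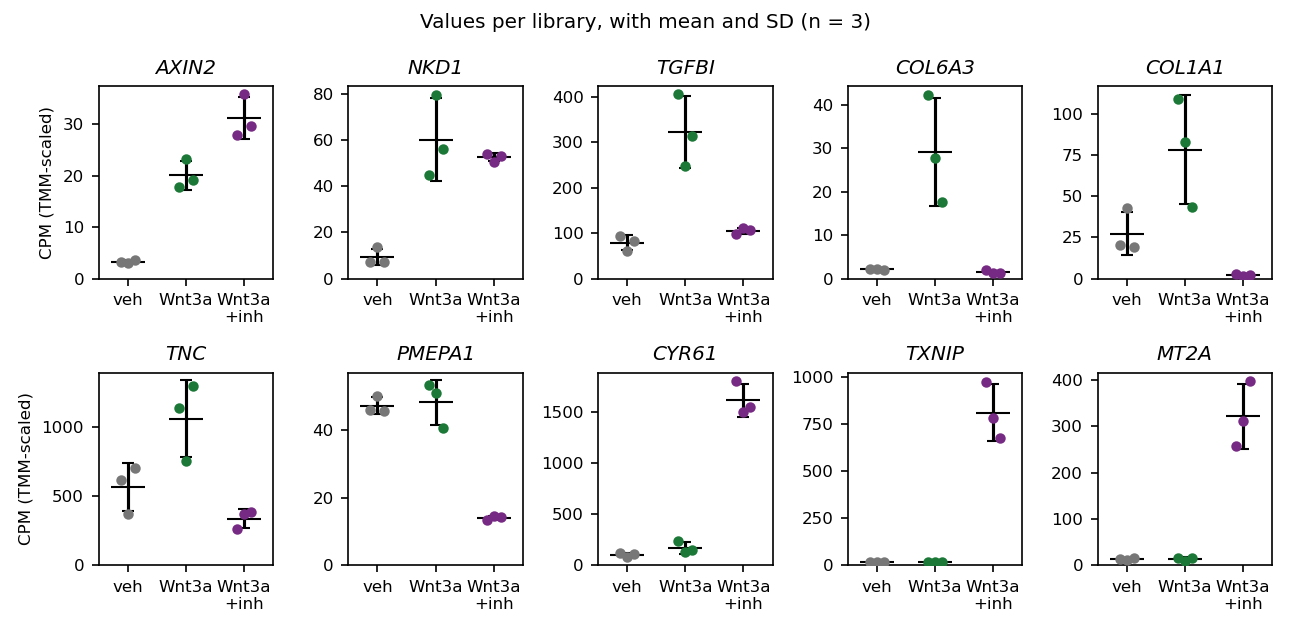
TMM-scaled CPM of 10 genes in each library (points), with the mean and SD of the 3 libraries of each group. AXIN2 and NKD1 were higher in the Wnt3a and inhibitor groups than in vehicle, TGFBI and COL6A3 were highest with Wnt3a alone, and TXNIP and MT2A were highest with the inhibitor.

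The second comparison, inhibitor against Wnt3a, asks what blocking TGF-β receptors does in Wnt3a-treated cells. Collagen genes were among the largest falls. COL1A1 fell from 78.4 ± 33.1 to 2.35 ± 0.633 CPM (SD, n = 3 per group; log2 -5.07, SE 0.457, edgeR adjusted p = 2.18e-05). COL1A2 fell from 40.1 ± 19.9 to 1.799 ± 0.745 CPM (log2 -4.49, SE 0.484, edgeR adjusted p = 5.86e-05) and COL6A3 from 29.2 ± 12.5 to 1.43 ± 0.372 CPM (log2 -4.36, SE 0.333, edgeR adjusted p = 8.97e-06). TXNIP, which binds thioredoxin and limits glucose uptake, rose from 15.2 ± 2.62 to 812 ± 153 CPM (log2 5.74, SE 0.183, edgeR adjusted p = 3.82e-07), and the metallothionein MT2A, a metal-binding protein, from 13.0 ± 3.58 to 322 ± 70.3 CPM (log2 4.63, SE 0.243, edgeR adjusted p = 2.08e-06). Of 17880 genes 4379 rose and 4634 fell in edgeR, 9013 or 50.4%, and 1308 and 2687 of them changed at least 2-fold.

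Of 30 collagens 0 rose and 12 fell (0 and 11 adjusted over the list alone; camera adjusted p = 0.00302, 0.69 with an estimated correlation), with 0 and 15 under library totals. COL5A1, a fibrillar collagen chain, fell from 132.9 ± 11.9 to 43.3 ± 3.95 CPM (edgeR adjusted p = 4.56e-06). Of 73 matrix glycoproteins 8 rose and 34 fell (8 and 34 adjusted over the list alone; camera adjusted p = 0.0131, 0.69 with an estimated correlation). The microfibril protein fibrillin 1, FBN1, fell from 276 ± 57.9 to 42.7 ± 3.81 CPM (log2 -2.69, SE 0.150, edgeR adjusted p = 2.83e-06), and the elastic fibre protein FBLN5 had a log2 fold change of -2.97 (edgeR adjusted p = 1.58e-05). TNC fell from 1065 ± 280.5 to 338 ± 68.8 CPM (log2 -1.66, SE 0.270, edgeR adjusted p = 0.000673), whereas FN1 (log2 -0.31, edgeR adjusted p = 0.176) and SPARC (log2 -0.31, edgeR adjusted p = 0.355) did not pass. FN1 was called lower with library totals and with log2(TPM + 1) (adjusted p = 0.0152 and 0.0103, up to 0.471 over the alternatives). Of 52 matrix-modifying genes 5 rose and 16 fell (5 and 16 adjusted over the list alone; camera adjusted p = 0.537; called lower with fry, fry adjusted p = 0.0063), 3 and 21 with library totals. They included a rise of the membrane protease MMP14 from 164 ± 7.44 to 354 ± 12.7 CPM (edgeR adjusted p = 6.5e-06) and a fall of the lysyl oxidase LOXL2 (log2 -3.31, edgeR adjusted p = 0.000298).

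Genes commonly induced by TGF-β moved both ways. Of 53, 10 rose and 20 fell (10 and 21 adjusted over the list alone; camera adjusted p = 0.263). The fry test called this list lower (fry adjusted p = 0.00501). PMEPA1 fell from 48.3 ± 6.66 to 13.98 ± 0.545 CPM (log2 -1.79, SE 0.119, edgeR adjusted p = 4.75e-06) and TGFBI from 322 ± 79.8 to 105 ± 6.55 CPM (log2 -1.62, SE 0.196, edgeR adjusted p = 0.000112). CYR61, a matricellular gene also known as a YAP target, rose from 167 ± 61.2 to 1612 ± 163 CPM (log2 3.27, SE 0.245, edgeR adjusted p = 8.2e-06). SMAD7 did not pass (log2 -0.27, SE 0.151, edgeR adjusted p = 0.157), but was called lower with library totals (log2 -0.53, adjusted p = 0.014), with log2(TPM + 1) (log2 -0.80, adjusted p = 0.00304) and with an effective length offset. Its adjusted p reached 0.407 over the 21 alternatives. Of 26 pathway components 9 rose and 7 fell (10 and 8 adjusted over the list alone; camera adjusted p = 0.976), which flips to 7 and 11 with library totals and 6 and 12 with log2(TPM + 1). Their median of -0.07 and mean of -0.01 lay on the other side of 0 from the test. SMAD4, the shared partner of receptor-activated SMADs, rose (log2 0.76, edgeR adjusted p = 4.11e-05), as did TGFB2, from 151 ± 27.7 to 334 ± 1.84 CPM (edgeR adjusted p = 5.76e-05), and the activin-binding FST fell (log2 -2.01, edgeR adjusted p = 5.01e-05).

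AXIN2 had 31.1 ± 4.10 CPM against 20.1 ± 2.82 (log2 0.63, SE 0.144, edgeR adjusted p = 0.00471), a rise not called with library totals or with log2(TPM + 1) (adjusted p up to 0.181). NKD1 had 52.7 ± 1.68 CPM against 60.3 ± 17.8 (log2 -0.20, SE 0.252, edgeR adjusted p = 0.54). WIF1 fell from 38.1 ± 7.75 to 6.91 ± 2.5 CPM (log2 -2.47, edgeR adjusted p = 6.14e-05). Of 32 Wnt targets 9 rose and 10 fell (10 and 11 adjusted over the list alone; camera adjusted p = 0.976), and their median of 0.02 and mean of -0.03 differ in sign. With library totals 6 rose and 12 fell. The mesenchymal transcription factor genes SNAI2 (log2 2.16, edgeR adjusted p = 0.000713; 2.78 without Wnt3a replicate 3, 4.44e-05) and TWIST1 (log2 1.11, edgeR adjusted p = 0.000298) were among the rises, and NKD2 (log2 -1.36, edgeR adjusted p = 0.000466) among the falls. Of 44 pathway components 10 rose and 12 fell (10 and 12 adjusted over the list alone; camera adjusted p = 0.732), 6 and 19 with library totals and 5 and 16 with log2(TPM + 1). They included PYGO2, a nuclear partner of β-catenin, at log2 -1.49 (edgeR adjusted p = 5.2e-06) and WLS, needed for Wnt secretion, at log2 0.87 (edgeR adjusted p = 5.48e-05).

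Of 45 factors promoting vessel growth 14 rose and 8 fell (14 and 8 adjusted over the list alone; camera adjusted p = 0.301; called higher with fry, fry adjusted p = 0.00493), 13 and 11 with library totals and 12 and 11 with log2(TPM + 1). VEGFA fell from 36.7 ± 6.94 to 19.2 ± 3.32 CPM (log2 -0.93, SE 0.160, edgeR adjusted p = 0.000915), as did ANGPTL2 (log2 -1.63, edgeR adjusted p = 1.45e-05) and ANGPTL4 (log2 -1.87, edgeR adjusted p = 1.74e-05), both angiopoietin-like. The Notch ligand JAG1 rose from 37.8 ± 4.603 to 108 ± 18.4 CPM (log2 1.51, edgeR adjusted p = 4.39e-05). Of 25 restraining factors 1 rose and 9 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.214; called lower with fry, fry adjusted p = 0.00169), including vasohibin 1, VASH1, at log2 -1.66 (edgeR adjusted p = 1.83e-05) and the semaphorin SEMA3F at log2 -1.88 (edgeR adjusted p = 0.000378).

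Among genes reported as activated by EWSR1-FLI1, 8 of 48 rose and 19 fell (8 and 19 adjusted over the list alone; camera adjusted p = 0.38), 3 and 23 with library totals and 1 and 24 with log2(TPM + 1). NKX2-2, a homeobox factor the fusion induces, fell from 72.3 ± 14.4 to 36.1 ± 3.56 CPM (log2 -1.003, SE 0.146, edgeR adjusted p = 0.000337). NR0B1 fell from 288 ± 50.6 to 200.1 ± 28.84 CPM (log2 -0.52, SE 0.162, edgeR adjusted p = 0.0212), a call lost without Wnt3a replicate 2 or inhibitor replicate 1 or 2 (adjusted p = 0.0908, 0.0588 and 0.0781; 0.00147 to 0.0908 over the alternatives). Of 39 genes reported as repressed 10 rose and 11 fell (10 and 11 adjusted over the list alone; camera adjusted p = 0.714), with a median of -0.01 and a mean of -0.03 against a test on the higher side, and 9 rose and 16 fell with library totals. CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 67.9 ± 21.4 to 569.5 ± 183 CPM (log2 3.07, SE 0.318, edgeR adjusted p = 4.75e-05).

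Genes of cell cycle arrest were among those that rose. Of 23 CDK inhibitors and p53 targets 16 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 7.27e-06, 0.481 with an estimated correlation). The kinase gene PLK3 rose from 13.5 ± 2.25 to 111 ± 4.21 CPM (edgeR adjusted p = 2.87e-06). BBC3, which promotes apoptosis, rose from 8.74 ± 0.451 to 106 ± 33.6 CPM (edgeR adjusted p = 4.6e-06) and the CDK inhibitor CDKN1B from 50.96 ± 3.44 to 122 ± 10.8 CPM (edgeR adjusted p = 1.02e-05). Of 32 immediate-early genes 21 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 6.55e-06, 0.69 with an estimated correlation). The MAP kinase phosphatase DUSP1 rose from 22.7 ± 1.75 to 271 ± 49.99 CPM (log2 3.58, SE 0.142, edgeR adjusted p = 4.66e-07). The transcription factor genes ATF3, from 13.3 ± 5.88 to 192 ± 28.2 CPM (edgeR adjusted p = 3.35e-05), and FOS, from 18.4 ± 6.44 to 118 ± 42.8 CPM (edgeR adjusted p = 0.000126), also rose. Of 23 YAP targets 14 rose and 4 fell (15 and 5 adjusted over the list alone; camera adjusted p = 0.00134, 0.339 with an estimated correlation). GADD45A, a growth arrest gene, rose from 18.8 ± 4.87 to 216 ± 63.0 CPM (edgeR adjusted p = 1.54e-05) and AMOTL2, a regulator of YAP, from 133 ± 7.53 to 408 ± 69.2 CPM (edgeR adjusted p = 3.28e-05). Of 32 interferon-induced genes 19 rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 6.55e-06, 0.69 with an estimated correlation), such as IRF9, a subunit of the interferon-activated factor ISGF3, from 14.9 ± 2.66 to 65.2 ± 8.69 CPM (edgeR adjusted p = 7.75e-06).

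Of 30 genes of the unfolded protein and amino acid stress response 11 rose and 10 fell (11 and 10 adjusted over the list alone; camera adjusted p = 0.597), which flips to 7 and 12 with library totals. Of 34 genes of hypoxia and glycolysis 10 rose and 9 fell (10 and 9 adjusted over the list alone; camera adjusted p = 0.561; called higher with fry, fry adjusted p = 0.0408), which flips to 9 and 11 with library totals and 6 and 11 with log2(TPM + 1).

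Proliferation genes split by phase. Of 34 S phase genes 3 rose and 20 fell (3 and 20 adjusted over the list alone; camera adjusted p = 0.000254, 0.818 with an estimated correlation). The G1/S cyclin CCNE2 fell from 37.3 ± 5.64 to 2.95 ± 1.29 CPM (log2 -3.64, SE 0.281, edgeR adjusted p = 9.45e-06) and FEN1, a nuclease of DNA replication, from 122 ± 12.3 to 31.4 ± 7.26 CPM (edgeR adjusted p = 1.56e-05). Of 40 genes of G2 and mitosis 28 rose and 2 fell (28 and 3 adjusted over the list alone; camera adjusted p = 2.37e-06, 0.69 with an estimated correlation), 19 and 4 with library totals. The centrosomal kinase NEK2 rose from 65.3 ± 14.5 to 302 ± 43 CPM (edgeR adjusted p = 1.41e-05), and the mitotic activator CDC20 from 190 ± 18.0 to 399 ± 7.59 CPM (edgeR adjusted p = 1.99e-05). Of 55 ribosomal protein genes 54 rose and 0 fell (55 and 0 adjusted over the list alone; camera adjusted p = 1.53e-15, 0.69 with an estimated correlation), 43 with library totals and 25 with log2(TPM + 1). RPLP0 rose from 3423 ± 149 to 5728 ± 535 CPM (edgeR adjusted p = 0.000125). Of 36 contractile and cytoskeletal genes 12 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.139; called higher with fry, fry adjusted p = 0.0408), which flips to 5 and 10 with library totals and 6 and 10 with log2(TPM + 1). The actin gene ACTG1 rose from 3906 ± 502 to 9119 ± 803 CPM (edgeR adjusted p = 2.3e-05) and the tropomyosin gene TPM1 fell (log2 -1.68, edgeR adjusted p = 0.000708). The contractile list passed as higher without Wnt3a replicate 1 (camera adjusted p = 0.0229, 0.0229 to 0.818 over the alternatives).

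**Figure D3:**
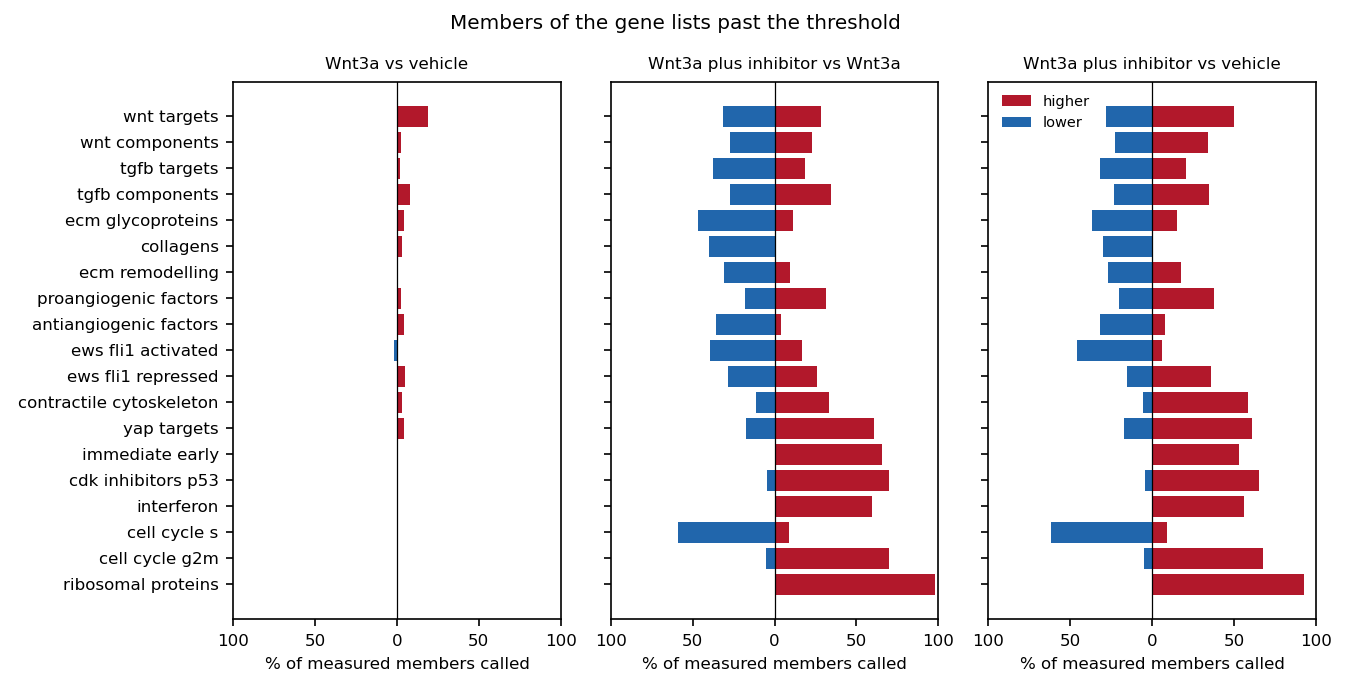
Percent of the measured members of 19 gene lists called higher (red) or lower (blue) by edgeR in each of the 3 comparisons. Ribosomal protein genes rose in 54 of 55 cases with the inhibitor against Wnt3a and S phase genes fell in 20 of 34. With library totals the balance flips for contractile genes (12 and 4 to 5 and 10) and TGF-β components (9 and 7 to 7 and 11) in that comparison, and for Wnt components (15 and 10 to 5 and 12) and TGF-β components (9 and 6 to 7 and 8) against vehicle.

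The largest single rises included more metallothioneins, whose near-identical copies can share reads: MT1G from 0.255 ± 0.0702 to 44.2 ± 16.6 CPM (log2 7.41), MT1F to 45.1 ± 14.8 CPM (log2 5.90) and MT1E to 29.7 ± 11 CPM (log2 4.91; edgeR adjusted p = 2.88e-06, 2.88e-06 and 1.79e-05). The adhesion gene NECTIN4 (log2 5.23, 5.83 without Wnt3a replicate 1), the stress cytokine GDF15 (log2 4.96, 6.57 without Wnt3a replicate 3), the kinase gene PLK2 (log2 4.25) and the cytokine IL24 (log2 4.14) also rose (edgeR adjusted p = 1.45e-05, 0.00251, 4.95e-05 and 9.05e-05). MTND1P23, a nuclear copy of a mitochondrial gene and thus uncertain, had log2 4.15, with 4.74 without Wnt3a replicate 1 and 3.03 without inhibitor replicate 1 (edgeR adjusted p = 0.00229). Among the falls, the pseudogene SLC2A3P1 had 0 counts with the inhibitor and 548 with Wnt3a alone, at least 128.4-fold lower, and LINC01614, a long noncoding RNA, 3 counts against 491, with 116 times as many in Wnt3a (39.3 to 562; edgeR adjusted p = 0.00716 and 9.33e-05). SLC2A3P1 is uncertain, since vehicle replicate 1 also had 0 counts, with 81 and 232 in vehicle replicates 2 and 3. LINC00968 (log2 -5.55, -6.50 and -4.92 without inhibitor replicate 1 and 2) and the antisense RHPN1-AS1 (log2 -4.48, -5.34 without inhibitor replicate 2), uncertain because the strand setting is not stated, also fell (edgeR adjusted p = 0.000189 and 0.000127). The pseudogene SSR4P1 (log2 -4.24), the proteoglycan gene ASPN (log2 -4.21, -3.62 without inhibitor replicate 3) and the mitochondrial histidine tRNA gene MT-TH (log2 -4.21) completed the set (edgeR adjusted p = 3.36e-05, 0.000426 and 0.00014).

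Markers of other cell types moved both ways: 0 of 5 endothelial markers rose and 2 fell, and 2 of 5 leukocyte markers rose and 2 fell. Of 6 epithelial markers 0 rose and 1 fell, and 1 of 10 fibroblast markers rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.516, 0.732, 0.694 and 0.516). The fry test called the endothelial, epithelial and fibroblast lists lower (fry adjusted p = 0.00501, 0.00493 and 0.0161). Of 13 mitochondrial mRNAs 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.984), which flips to 2 and 5 with library totals, and their median of 0.08 and mean of -0.10 differ in sign. Of 14 nuclear-retained or non-polyadenylated RNAs 1 rose and 2 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.771). With library totals the nuclear counts were 0 and 2 and the fibroblast counts 0 and 5. Library totals and log2(TPM + 1) moved the median of all genes by -0.25 and -0.27, so that 2828 genes rose and 6425 fell with the first (30.6% higher) and 2293 and 6352 with the second (26.5%), against 48.6% with TMM factors. The changes above are relative to the TMM scale and were measured in the libraries with fewer detected genes described at the start.

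The genes changed by Wnt3a were then followed into the inhibitor comparison. Of the 71 that had risen 23 fell with the inhibitor, 24 rose further and 24 were not called, and of the 4 that had fallen MGP rose and 3 were not called, all at the edgeR threshold. The 24 that moved back included COL6A3, TGFBI, WIF1, THBS1, SYTL2, PARVG, MATN3 and KRT81. Those that moved further the same way included AXIN2, TGFB2, ITGB8, FOXQ1 and the metallothionein MT1X, and those not called NKD1, TSHZ1, FZD7 and TCF7. Random gene sets matched on expression and direction had a mean of 19.4 genes moved back, with 13.6% of sets at 24 or more, and 21.5 moved further the same way, with 29.4% of sets at 24 or more. Both comparisons use the Wnt3a libraries. With unchanged groups simulated against them, the correlation of fold changes across genes, which are not independent replicates, was -0.487, against an observed -0.232. In that simulation 0 genes moved back. It held no true change in either comparison and so had few or no genes to move back, and this 0 decides nothing about the observed 24. The covariance was -0.121 against a simulated -0.085, a difference of -0.036. The number moved back was 11 and 8 without vehicle replicate 1 and 3, 11 without Wnt3a replicate 2, and 60 without inhibitor replicate 1, where 140 genes changed with Wnt3a. The genes that had risen divided into 32 that fell and 16 that rose further with library totals, 30 and 11 with log2(TPM + 1), and 14 and 4 at an absolute log2 fold change of at least 1. The 24 moved further the same way became 10, 14 and 9 without vehicle replicate 1, 2 and 3, 14, 12 and 15 without Wnt3a replicate 1, 2 and 3, and 37 and 14 without inhibitor replicate 1 and 2. The shared Wnt3a libraries can add to the number moved back.

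**Figure D4:**
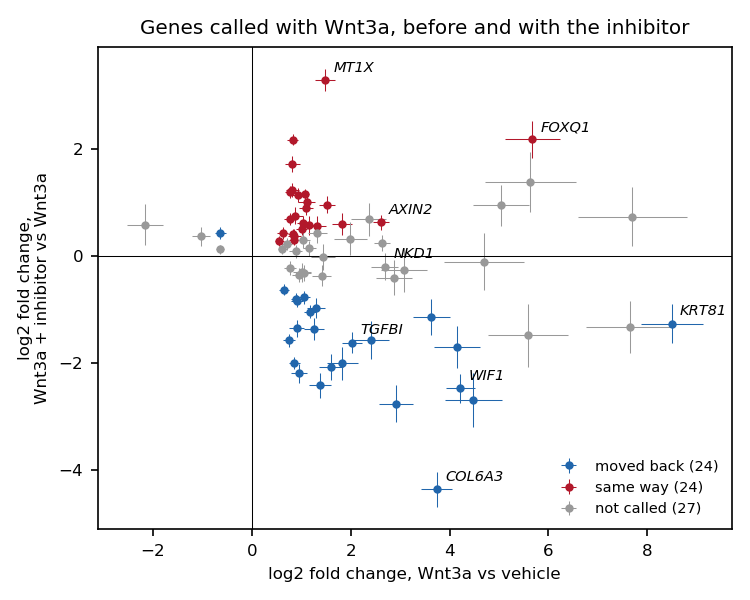
Log2 fold change of the 75 genes changed by Wnt3a, against vehicle (horizontal) and for the inhibitor against Wnt3a (vertical), with bars of 1 SE. The plot separates 24 genes moved back, 24 moved further the same way and 27 not called with the inhibitor.

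The last comparison, inhibitor against vehicle, asks what differed from untreated cells when Wnt3a and the inhibitor were both present. AXIN2 rose from 3.29 ± 0.326 to 31.1 ± 4.10 CPM (SD, n = 3 per group; log2 3.24, SE 0.161, edgeR adjusted p = 1.45e-06) and NKD1 from 9.33 ± 3.59 to 52.7 ± 1.68 CPM (log2 2.495, SE 0.271, edgeR adjusted p = 5.82e-05). TGFBI had 105 ± 6.55 CPM against 79.1 ± 16.9 (log2 0.41, SE 0.192, edgeR adjusted p = 0.103), called higher with genes of at least 1 count kept (adjusted p = 0.0449; up to 0.424 over the alternatives). COL1A1 fell from 27.3 ± 13.3 to 2.35 ± 0.633 CPM (log2 -3.55, SE 0.437, edgeR adjusted p = 0.000121) and PMEPA1 from 47.2 ± 2.52 to 13.98 ± 0.545 CPM (log2 -1.75, SE 0.119, edgeR adjusted p = 4.73e-06). In edgeR 4462 genes rose and 4433 fell, 8895 or 49.7% of those tested.

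Of 32 Wnt targets 16 rose and 9 fell (17 and 9 adjusted over the list alone; camera adjusted p = 0.23; called higher with fry, fry adjusted p = 0.0105), 9 and 8 with log2(TPM + 1), with TCF7 from 3.57 ± 0.841 to 17.8 ± 5.82 CPM (edgeR adjusted p = 0.000293) and FZD7 at log2 1.31 (edgeR adjusted p = 5.4e-05). Of 44 Wnt components 15 rose and 10 fell (15 and 10 adjusted over the list alone; camera adjusted p = 0.774), which flips to 5 and 12 with library totals and 4 and 10 with log2(TPM + 1), and their median of 0.16 and mean of -0.06 differ in sign. The receptor gene FZD4 was at log2 -1.96 (edgeR adjusted p = 0.00012). Of 53 TGF-β targets 11 rose and 17 fell (11 and 17 adjusted over the list alone; camera adjusted p = 0.757). CYR61 (log2 4.00, SE 0.253, edgeR adjusted p = 3.71e-06) and the transcription factor gene ZEB1 (log2 1.74, edgeR adjusted p = 6.17e-06) rose, and SMAD7 did not pass (log2 0.16, edgeR adjusted p = 0.415) except without inhibitor replicate 1 (log2 0.31, adjusted p = 0.0426; up to 0.86 over the alternatives). Of 26 TGF-β components 9 rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.64; called higher with fry, fry adjusted p = 0.0105), which flips to 7 and 8 with library totals. TGFB2 rose from 79.2 ± 4.84 to 334 ± 1.84 CPM (log2 2.08, edgeR adjusted p = 3.24e-06).

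Of 30 collagens 0 rose and 9 fell (0 and 9 adjusted over the list alone; camera adjusted p = 0.11; called lower with fry, fry adjusted p = 0.0447). Of 73 matrix glycoproteins 11 rose and 27 fell (11 and 27 adjusted over the list alone; camera adjusted p = 0.251). FBN1 fell (log2 -2.15, edgeR adjusted p = 4.76e-06), and CTGF, a matricellular growth factor, rose from 136 ± 28.98 to 499 ± 28.9 CPM (edgeR adjusted p = 4.08e-05). TNC was at 338 ± 68.8 CPM against 565 ± 176 (log2 -0.74, SE 0.265, edgeR adjusted p = 0.0394), a call lost without vehicle replicate 1 or 3 or without any inhibitor replicate (adjusted p = 0.0566 to 0.149; 0.000587 to 0.149 over the alternatives). FN1 (log2 0.00, edgeR adjusted p = 0.989) and SPARC (log2 0.27, edgeR adjusted p = 0.417) did not pass. Of 52 matrix-modifying genes 9 rose and 14 fell (9 and 14 adjusted over the list alone; camera adjusted p = 0.831), 5 and 17 with library totals. Of 45 factors promoting vessel growth 17 rose and 9 fell (17 and 9 adjusted over the list alone; camera adjusted p = 0.222; called higher with fry, fry adjusted p = 0.0027), and of 25 restraining factors 2 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.519; called lower with fry, fry adjusted p = 0.00707), 1 and 10 with library totals. VEGFA (log2 -0.81, edgeR adjusted p = 0.00211), ANGPTL4 (log2 -2.71, edgeR adjusted p = 3.24e-06) and SEMA3F (log2 -2.85, edgeR adjusted p = 3.57e-05) fell, and JAG1 rose (log2 1.97, edgeR adjusted p = 1.07e-05).

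Of 48 genes reported as activated by EWSR1-FLI1 3 rose and 22 fell (3 and 22 adjusted over the list alone; camera adjusted p = 0.0237, 0.797 with an estimated correlation), 0 and 27 with library totals. The list call was lost without vehicle replicate 1 or inhibitor replicate 1 (camera adjusted p = 0.0546 and 0.0598; 0.00369 to 0.797 over the alternatives). NKX2-2 fell from 99.7 ± 6.57 to 36.1 ± 3.56 CPM (log2 -1.47, SE 0.148, edgeR adjusted p = 3.73e-05) and NR0B1 from 387 ± 64.9 to 200.1 ± 28.84 CPM (log2 -0.95, SE 0.163, edgeR adjusted p = 0.000897). Of 39 reported as repressed 14 rose and 6 fell (14 and 6 adjusted over the list alone; camera adjusted p = 0.159; called higher with fry, fry adjusted p = 0.0275), 10 and 7 with library totals, with CDKN1A at log2 2.80 (edgeR adjusted p = 7.11e-05). Of 30 unfolded protein and amino acid stress genes 11 rose and 9 fell (12 and 10 adjusted over the list alone; camera adjusted p = 0.799), which flips to 8 and 12 with library totals. Of 34 hypoxia and glycolysis genes 8 rose and 11 fell (10 and 11 adjusted over the list alone; camera adjusted p = 0.997), with a median of 0.05 and a mean of -0.06 that differ in sign, and 6 rose and 15 fell with library totals. Lists with preset-correlation calls that were lost with an estimated one were YAP targets (14 rose and 4 fell; camera adjusted p = 0.000168, then 0.271), contractile genes (21 and 2; 0.00182, then 0.797) and CDK inhibitors and p53 targets (15 and 1; 2.08e-05, then 0.532). Further such lists were immediate-early genes (17 and 0; 9.81e-05, then 0.797), interferon-induced genes (18 and 0; 4.18e-05, then 0.797) and S phase genes (3 and 21; 2.08e-05, then 0.797). The last were genes of G2 and mitosis (27 and 2; 1.86e-06, then 0.797) and ribosomal proteins (51 and 0; 2.58e-11, then 0.797). In that order, 15 and 4, 21 and 2, 15 and 1, 18 and 0, 18 and 0, 3 and 21, 29 and 2, and 52 and 0 rose and fell adjusted over the list alone. DUSP1 (log2 3.70, edgeR adjusted p = 3.9e-07), SESN1, a stress-induced sestrin (log2 2.72, edgeR adjusted p = 2.47e-06), and IRF9 (log2 1.93, edgeR adjusted p = 1.13e-05) rose. ACTG1 (log2 1.15, edgeR adjusted p = 2.94e-05) and NEK2 (log2 2.27, edgeR adjusted p = 1.13e-05) also rose. FEN1 (log2 -2.10, edgeR adjusted p = 1.05e-05) and CCNE1, a G1/S cyclin (log2 -3.34, edgeR adjusted p = 1.59e-05), fell.

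Among the largest rises were FOXQ1, with 438 counts against 2 (ratio 280, 95% interval 77.2 to 2320), and KRT81, with 166 against 1 and uncertain as above (ratio 213, 37.6 to 8450; edgeR adjusted p = 4.98e-06 and 1.87e-05). MT1G (log2 7.34), TXNIP (log2 5.83) and IL24 (log2 5.75, 6.36 without vehicle replicate 3) were also among them (edgeR adjusted p = 3.18e-06, 3.58e-07 and 2.61e-05). Among the largest falls were LINC01614, with 3 counts against 386 (100 times as many in vehicle, 34.1 to 489), and RHPN1-AS1 (log2 -4.49, -5.35 without inhibitor replicate 2; edgeR adjusted p = 0.000111 and 0.000123). SSR4P1 (log2 -4.38), the ankyrin repeat gene ANKRD63 (log2 -4.19, -4.82 without inhibitor replicate 3) and LINC01521 (log2 -4.09) were also among them (edgeR adjusted p = 2.72e-05, 0.000613 and 1.01e-05).

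Of the markers, 0 endothelial rose and 2 fell, 1 leukocyte rose and 1 fell, 0 epithelial rose and 2 fell, and 1 fibroblast rose and 2 fell (camera adjusted p = 0.297, 0.937, 0.44 and 0.997). The fry test called the endothelial and epithelial lists lower (fry adjusted p = 0.0027 and 0.00294). The fibroblast counts were 1 and 0 adjusted over the list alone, and the others were the same. The fibroblast median of -0.10 and mean of 0.01 differ in sign, as do the mitochondrial median of 0.09 and mean of -0.07. Of mitochondrial mRNAs 5 rose and 4 fell and of nuclear RNAs 0 and 2 (6 and 5, and 0 and 0, adjusted over the list alone; camera adjusted p = 0.997 and 0.903). The mitochondrial counts flip to 4 and 5 with library totals, and the contractile counts of 21 and 2 became 13 and 5. With log2(TPM + 1) the S phase counts were 0 and 24 and the leukocyte counts 1 and 2. With library totals 3061 genes rose and 6036 fell (33.6% higher) and with log2(TPM + 1) 2722 and 5462 (33.3%), against 50.2% with TMM factors, and the median of all genes moved by -0.23 and -0.21. Wnt3a alone gave few calls, with 75 genes changed from vehicle, against 9013 between inhibitor and Wnt3a. No group shows the inhibitor without Wnt3a, so its effect in the absence of the ligand was not measured.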

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

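The tests of overlap size, of a shared batch and of nuclear RNA were chosen after the results they address were seen, and the bound for the nuclear RNA test was amended after its result.

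The effective length per gene, which the comparisons above did not use, shifted between groups. RSEM derives it from the lengths of the transcripts to which it assigns reads. With limma over 14085 genes, 3 genes differed between Wnt3a and vehicle (0 longer and 3 shorter: ZNF385D, GFOD1 and MNT). Between inhibitor and Wnt3a 642 differed (269 longer and 373 shorter), and between inhibitor and vehicle 523 (169 and 354). Unadjusted p under 0.05 was met by 470, 5270 and 5044 genes. The effective length of VMA21, a chaperone of the vacuolar proton pump picked after its values were seen, was 1473 ± 89 bases with the inhibitor and 4577 ± 93 with Wnt3a (SD, n = 3).

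With the inhibitor, 9013 genes differed from Wnt3a and 8895 from vehicle, and in each case the other splits of the 6 libraries gave at most 0, with 1 of 10 splits as large, and 10 splits are too few for a share under 0.05. Thinning every library to the lowest total left 8883 genes against Wnt3a, and correction for GC content and length left 9491, which argues against either as the whole cause. The inhibitor is the difference that the design names between these libraries, and no label names a batch. The first component, with 56.5% of the variance, parts the inhibitor libraries along their group, so it says nothing about handling apart from the treatment, which these 9 libraries do not test.

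Noncoding classes were lower with the inhibitor against Wnt3a: 2185 antisense, lincRNA and related genes had a median log2 fold change of -0.954, with 834 lower and 126 higher in edgeR. Of these 2185 noncoding genes, 1124 are antisense genes, whose values are uncertain because the strand setting of the counting is not given in the sources used here. The 745 lincRNA genes alone had a median of -1.1, and all noncoding genes are considered together below. The 910 of them with a mean of at least 1 CPM had a median of -0.673. The intervals in this paragraph come from 1000 resamples of genes, so they do not cover the spread between libraries. Protein-coding genes of matched mean CPM had a median of -0.506, and the difference of -0.448 (95% interval -0.53 to -0.373) argues, across these genes, against low expression as the whole cause. After correction for GC content and length the median was -1.053 (-1.108 to -0.985), which argues against that bias as the whole cause. A lower yield of nuclear RNA may contribute and cannot be told apart, since the nuclear-retained list had a median of -0.221 (-0.658 to 0.112) with 1 member higher and 2 lower, and a response to the inhibitor stays open, untested.

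Of 75 genes changed by Wnt3a, 24 moved back with the inhibitor, and random gene sets matched on expression and direction gave a mean of 19.4 (central 95% 12 to 27), so the breadth of the inhibitor comparison is a candidate explanation for this number. In 100 assignments of the 9 libraries, the real one included, 3 gave as many, but 96 of the 99 others selected 0 genes in edgeR and so had none to move back, and this count decides nothing about chance. The highest other gave 95, with the inhibitor libraries as 1 group and the other 6 parted as in the split with 315 genes below. The number without vehicle replicate 1 and 3 was 11 and 8, without Wnt3a replicate 2 it was 11, and without inhibitor replicate 1 it was 60.

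For Wnt3a against vehicle, 2 of the 10 splits of the 6 libraries gave as many genes as the real 75. The highest other, vehicle replicates 1 and 3 with Wnt3a replicate 3 against the rest, gave 315, which points to a structure of the samples. Gene lists past the camera threshold numbered 15 with a highest other of 12 (1 split as large) for Wnt3a against vehicle, 9 with a highest other of 10 (5 splits) for inhibitor against Wnt3a, and 9 with a highest other of 9 (3 splits) for inhibitor against vehicle. In each case 10 splits are too few for a share under 0.05. For both inhibitor comparisons, other splits that mixed the treatments passed as many lists as the real one. The number of lists past the preset camera threshold therefore does not set the real grouping apart there.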

How the results depend on the processing

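The fits to protein-coding genes, thinned counts, GC and length correction and without vehicle replicate 2 and Wnt3a replicate 2 were chosen after the data were seen. Genes changed by Wnt3a, 75 as reported, numbered 259 with genes of at least 1 count kept, 299 with DESeq2, 30 at adjusted p under 0.01, 49 with an absolute log2 fold change of at least 1, 15 without vehicle replicate 2 and Wnt3a replicate 2 together, 20 to 60 without 1 library of the groups compared and 140 without inhibitor replicate 1. In the same order the genes moved back, 24 as reported, numbered 99, 112, 11, 14 and 5, and 8 to 60 without 1 library of any group. The sign of the inhibitor's change against a held-out Wnt3a library was opposite for 21 of 48 genes with replicate 1, 14 of 32 with replicate 2 and 39 of 64 with replicate 3, against 39 of 75 as reported. With an absolute log2 fold change of at least 1, the inhibitor comparisons gave 3995 genes against Wnt3a and 3960 against vehicle, and without 1 library 7411 to 9613 and 7575 to 9262. Gene lists past the threshold numbered 0, 0 and 0 for camera with an estimated correlation and 6, 21 and 21 for fry, in the order of Wnt3a against vehicle, inhibitor against Wnt3a and inhibitor against vehicle, and without 1 library 13 to 20, 9 to 10 and 8 to 9. Fewer genes or libraries follow from the construction of the stricter thresholds and left-out libraries, and for the rest the cause was not tested. Among results for named genes, 1591 stayed called or stayed uncalled, 63 gained and 86 lost a call for Wnt3a against vehicle. The inhibitor comparisons had 1936, 5 and 5 against Wnt3a, and 1769, 3 and 9 against vehicle. Direction was compared only for genes called as reported. Uncalled genes could change sign, as PMEPA1 did for Wnt3a against vehicle (log2 -0.041 to 0.141 over the alternatives). No named gene called as reported took the opposite direction in any alternative run. The balance of called list members flipped with library totals for several lists, such as contractile genes with the inhibitor against Wnt3a (12 higher and 4 lower to 5 and 10).

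Same-numbered libraries did not deviate together in every pair of groups, so the numbers were not taken to pair the libraries. Correlations were 0.015, 0.416 and 0.353 for vehicle with Wnt3a, against -0.453 to 0.209 for differently numbered libraries. For Wnt3a with inhibitor they were 0.325, -0.165 and 0.205, against -0.379 to 0.306. For vehicle with inhibitor they were -0.033, -0.182 and 0.082, against -0.195 to 0.183. Replicates 2 and 3 of vehicle and Wnt3a thus correlated above every differently numbered pair of those groups, and a pairing there was not ruled out. With the replicate number as a block the counts were 79, 9166 and 9039 genes, 26 moved back and 19, 9 and 9 lists, and FOLR2, DNAH11 and MGP had edgeR adjusted p = 0.0902, 0.0719 and 0.053 for Wnt3a against vehicle. The block added calls for ITGA11 in that comparison and TGFBI for inhibitor against vehicle (edgeR adjusted p = 0.049 and 0.047), and for the proteoglycan, matrix-modifying, vessel-restraining and immediate-early lists for Wnt3a against vehicle. In simulated counts at this depth, with few genes changed and all of them at a mean of at least 1 CPM, 35, 32 and 32 of 50 genes changed 2-fold were called, and 8, 7 and 7 of those changed 1.5-fold. Thinning every library to the lowest total left 73 genes for Wnt3a against vehicle and 8883 for inhibitor against Wnt3a.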

Other observations

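The families below were chosen after the values were seen. All 7 metallothionein genes tested, which bind zinc and copper, were higher with the inhibitor than with Wnt3a in edgeR, and all 7 also with library totals and with log2(TPM + 1). MT1X had 152 ± 33.1 CPM against 15.6 ± 3.61 (SD, n = 3). MT1H and MT1M had 1.55 ± 0.937 and 1.12 ± 0.513 CPM with the inhibitor and are listed at 0 counts in the other groups. Both therefore passed the filter on low counts through the inhibitor libraries alone and could be called only higher.

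Mitochondrial transcripts moved both ways between inhibitor and Wnt3a. Of 17 mitochondrial tRNA genes on both strands 0 rose and 12 fell. Some of these falls were near the floor, such as MT-TV at 0.326 ± 0.0461 CPM with Wnt3a, whereas MT-TN had 55.5 ± 6.79 CPM there. Of 9 light-strand genes, MT-ND6 and 8 tRNAs, 0 rose and 7 fell, 0 and 8 with library totals and with log2(TPM + 1). MT-ND6, the light-strand mRNA, fell from 635 ± 52.6 to 105 ± 26 CPM (log2 -2.60, edgeR adjusted p = 6.39e-06). Of 12 heavy-strand mRNAs 5 rose and 3 fell, which flips to 2 and 4 with library totals and 0 and 4 with log2(TPM + 1). Of 11 heavy-strand tRNA and ribosomal RNA genes 2 rose, both ribosomal RNAs, and 6 fell, 2 and 7 with library totals and 2 and 8 with log2(TPM + 1). The large ribosomal RNA MT-RNR2 rose from 5050 ± 525 to 14100 ± 452 CPM (log2 1.48, edgeR adjusted p = 4.22e-06). The strand setting of the counting is not given in the sources used here, so reads of the opposite strand were not ruled out for these genes.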
